A study of Mus musculus with 3 samples.

How the data were processed

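RNA of mouse thymocytes was measured on 3 Affymetrix whole-transcript arrays: 1 from a wild type mouse, 1 from a β-catenin transgenic mouse and 1 from a TCF-1-deficient mouse. Per the labels' protocols, thymocytes were passed through a cell strainer, total RNA was extracted with a column kit, and biotinylated cRNA was made by the manufacturer's sense target labelling assay. No protocol mentions a sort or gate, so the values are for the whole thymocyte suspension.

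The deposited table holds 35556 probe sets, each with 1 value per array. The deposited values were taken as log2 values: per the submitters' processing notes, RMA and Partek were used, RMA ends in log2 values, and the deposited values run from 1.73 to 14.8. No header states the log base. The versions, the settings, the background correction and the genome build are not given in the sources used here. The medians over all probe sets were 6.73 for wild type, 6.65 for transgenic and 6.60 for TCF-1-deficient. The medians over named genes were 6.86, 6.87 and 6.91. The deposited normalisation was kept, and the median difference over genes was 0 in each comparison.

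A feature of the deposited values limits small differences. Of the 35556 probe sets, 10229 (28.8%) have the same value on all 3 arrays to the last printed digit. Over genes, 53.3% have identical values on the transgenic and wild type arrays, and 36.4% on the TCF-1-deficient and wild type arrays. A difference of exactly 0 is therefore not a measured equality of that precision.

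Probe sets were named from the platform's annotation table. It lists 23410 of the probe sets, of which 21789 have 1 gene symbol and 1621 have several. The other 12146 are unnamed here. Of the probe sets with 1 symbol, 99.6% had an Entrez identifier in the GRCm38.p6 gene table, and 0 symbols needed updating. Probe sets with several symbols were not used. The 21789 probe sets represent 19938 genes, and for the 999 genes with more than 1 probe set the one with the highest mean over the 3 arrays was taken. Columns of samples outside this series numbered 0. Of the 9 genes fixed to be reported in any case, 7 had a named probe set. The gene disrupted in the TCF-1-deficient mice was not analysed here.

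Each genotype has 1 array. No error, p-value or test across samples can be given, and the number of arrays limits the precision of every value. Differences are log2 values of one array minus another, and folds are 2 to the power of the difference. Genes are called higher or lower at a difference of at least 1 on the log2 scale, which is 2-fold, and this is a rule of size. For gene lists, the median difference over the measured members was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins (seed 20240). A list was said to stand apart below percentile 2.5 or above percentile 97.5. This describes these arrays and is not evidence about the genotypes. Because many differences are exactly 0, medians of random lists lie close to 0, and a list can stand apart with a small median.

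The design, the size rule, 34 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison with wild type, the 10 genes with the largest difference in each direction among genes whose mean level is at least the median over genes (6.90), leaving out predicted genes, clone names, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors. It adds up to 20 genes for the combination of lower without TCF-1 and higher with the transgene, the genes fixed in any case, and up to 5 members per list. Genes named outside it were chosen after their values were seen, and are said to be so.

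The calculations were checked on simulated arrays for the comparison of TCF-1-deficient with wild type, with all 19938 genes and a noise SD of 0.15. Of 100 genes changed 3-fold, 100 passed the 2-fold rule, and of 100 genes changed 1.5-fold, 2 passed. Of 100 unchanged lists of 20 genes, 7 stood apart. All 100 stood apart after a shift of 0.5. That shift is large beside a noise SD of 0.15, so this outcome was close to certain. The simulated noise gave no identical values between arrays, unlike the deposited values. The rate of 7 in 100 therefore does not tell how easily a list stands apart in the deposited data.

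The alternatives were thresholds of 1.5-fold and 3-fold, a filter on dim genes, removal of an intensity trend by loess (span 0.3), centring of each array on its median over all probe sets, other rules for genes with several probe sets, the mean in place of the median, and unmatched random lists. Leaving out the genes of chromosomes X and Y, and leaving out genes with identical values, were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.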

Results

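Gene expression was profiled in thymocytes, the developing T cells of the thymus, from mice of 3 genotypes. TCF-1 is a transcription factor that acts with β-catenin in the Wnt pathway, and the study compared mice without TCF-1 and mice carrying a β-catenin transgene with wild type mice. There was 1 array per genotype and no replicate, so the values below carry no error and none of the differences has a replicate check. The mice also differed in age as the labels give it: 12 weeks for wild type, 16 weeks for the transgenic and 8 weeks for the TCF-1-deficient. Values are the deposited log2 values, and differences are in log2 units.

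The arrays were first compared with their labels. The TCF-1-deficient label was not checked, since the gene disrupted in these mice was not analysed here. Ctnnb1, which encodes β-catenin, was at 11.15 on the wild type array, 11.39 on the transgenic array and 11.16 on the TCF-1-deficient array. The transgenic array was thus 0.24 higher than wild type (1.18-fold), under the 2-fold rule. Whether the probes of this set match the transgene's transcript is not stated, so this level does not check the label. Transcripts specific to one sex differed between the arrays. Xist, which is expressed from the inactive X chromosome of females, was at 12.49 on the wild type array, 12.17 on the TCF-1-deficient array and 4.86 on the transgenic array. The Y-linked genes Uty, Eif2s3y and Kdm5d were higher on the transgenic than on the wild type array by 4.62, 4.70 and 2.58. Genotype, age and this sex-linked difference cannot be separated in the transgenic comparison.

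The first comparison asked which genes depend on TCF-1. On the TCF-1-deficient array, genes of CD4+CD8+ double-positive thymocytes were lower than on the wild type array. Genes of Notch signalling, many of them also markers of the earlier DN3 stage, were higher. Cd4, the co-receptor that marks these cells, was lower by 13.4-fold (12.87 against 9.13). Heyl and Dtx1, genes induced by Notch, were higher by 3.19 and 3.03. Of 19938 genes, 523 were lower and 266 were higher by at least 2-fold. With each array centred on its median, which moves the median over genes by 0.13, the numbers were 405 and 364. This shift comes from the medians over all probe sets, 6.73 for wild type and 6.60 for TCF-1-deficient. Over named genes the medians were 6.86 and 6.91, so the shift does not come from the named genes.

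Of the 23 measured double-positive genes, 14 were lower by at least 2-fold and 0 were higher. Their median difference of -1.44 lay below those of all 10000 matched random lists, of which 95% lay between -0.33 and 0.02. Besides Cd4, the largest differences were in Bcl6, a transcriptional repressor (-2.58), Slamf1, a co-stimulatory receptor (-2.26), Cd8b1, a chain of the CD8 co-receptor (-2.10), and Rag1, a subunit of the recombinase that assembles antigen receptor genes (-1.95). Of 13 Notch readouts, 9 were higher and 0 lower, with a median of 1.54. They included Hes1, a repressor induced by Notch (2.74), Il2ra, the α chain of the IL-2 receptor (2.06), and Ptcra, the pre-TCR α chain (1.79). Of 16 DN3 genes, 9 were higher and 1, Rag1, was lower, with a median of 1.16. The DN3 and Notch lists share 8 genes and are not independent. Heyl, Dtx1, Hes1, Il2ra, Ptcra, Notch3 and Notch1 are in both lists and make up most of the higher DN3 genes. The higher DN3 genes are thus mostly Notch readouts, and the lower quartile of the DN3 list was -0.22. The DN3 and Notch medians both lay above those of all random lists. Early progenitor genes did not stand apart, with a median of 0.03 over 19 genes. Of the 19, 8 did not reach the median level over genes on any array, and 6 were identical on the TCF-1-deficient and wild type arrays. Cd93 (1.88) and Mef2c (1.21) were higher by at least 2-fold, and Cd44, the hyaluronan receptor, had the next largest difference (-0.91).

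Of 26 single-positive genes, which mark the stages after the double-positive stage, 6 were lower on the TCF-1-deficient than on the wild type array by at least 2-fold and 0 higher. At 1.5-fold, 11 were lower and 3 higher. The median was -0.32 at percentile 0.13 of the random lists. The transgenic array had a like median against wild type (-0.30), and the transgenic minus TCF-1-deficient median of 0.13 did not stand apart (percentile 93.7). The lower single-positive genes on the TCF-1-deficient array included Cd69, an early activation marker (-2.24), Cd52 (-1.66) and Cd40lg, the ligand of CD40 (-1.62). Of 22 genes induced through the T cell receptor, 9 were lower and 2 higher, with a median of -0.91. Egr2 (-2.29) and Nr4a3 (-1.87), both transcription factors, were among the lowest, and Pdcd1, the inhibitory receptor PD-1, was higher by 1.47. Of 20 immediate early and heat-shock genes, which also follow cell isolation, 6 were lower and 0 higher, with a median of -0.56. Fosb (-1.95), Zfp36 (-1.83) and Jund (-1.80) had the largest differences. Both medians lay below those of all random lists. The T cell receptor-induced list shares Cd69, Cd40lg and Cd5 with the single-positive list, and Egr1 and Nfkbia with the immediate early list. These lists are not independent. For the immediate early list the transgenic minus TCF-1-deficient median of 0.023 did not stand apart (percentile 89.3). In that comparison 4 members were higher by at least 2-fold and 0 lower, while Fosb and Fos differed by -0.13 and -0.12. The lower level of this list therefore cannot be tied to TCF-1, since a difference of the wild type array or of cell isolation cannot be told apart from it. Of 18 genes of the T cell receptor complex, 2 were lower by at least 2-fold, Grap2 (-1.07) and Cd28 (-1.06), and at 1.5-fold 9 were lower and 2, Fyn (0.66) and Cd3d (0.60), higher, with a median of -0.54 at percentile 0.09. Of 30 transcription factors of the T lineage, 7 were lower and 1 was higher, and the median of -0.13 did not stand apart. Besides Bcl6 and Egr2, the largest differences were in Sox13, a factor of γδ T cells (1.95), E2f2, a regulator of the cell cycle (-1.79), and Ets2 (-1.51).

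The series' design also named cell death. Among genes of the BCL-2 family, Bcl2l1, which encodes the pro-survival protein BCL-XL, was lower on the TCF-1-deficient array by 3.14-fold, from 10.23 to 8.58. Bcl2l1 is also a member of the double-positive list, whose median was -1.44. Its difference is therefore not separate from the lower level of that list. Mcl1, another pro-survival member, was lower by 0.71 and Bcl2 by 0.24. Bcl2l1 was the 1 of 5 measured pro-survival members beyond 2-fold, and the list's median of -0.24 did not stand apart (percentile 6.08). None of the 12 pro-apoptotic members was beyond 1.5-fold in either direction, and Bnip3 (-0.57) had the largest difference. Of 25 death receptor and caspase genes, 2 were lower and 0 higher by at least 2-fold. They were Fas, the death receptor (-2.60), and Tnfrsf1a, a TNF receptor (-1.51). Cflar, an inhibitor of death receptor signalling, was lower by 0.86, and Tnfsf10, the death ligand TRAIL, was higher by 0.80. Of 20 p53 targets, 4 were lower, with Fas the lowest, and 2 were higher, Plk2 (1.36) and Phlda3 (1.28). The medians of the last 3 lists were 0.

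Readouts of Wnt signalling differed in both directions without TCF-1. Of 28 measured readouts, 6 were higher and 3 lower by at least 1.5-fold, and 5 were higher by at least 2-fold: Ccnd1, cyclin D1 (1.23), Tnfrsf19 (1.18), Fzd7, a Wnt receptor (1.17), Apcdd1 (1.13) and Myc (1.10). Axin2, a negative regulator induced by the pathway, was at 9.22 against 8.23, a difference of 0.99. Lef1, the related factor, was higher by 0.54. Myc is also among the higher Notch readouts, so its difference is not separate from that list. The 3 lower readouts were Ccnd2, cyclin D2 (-1.01), Cd44 (-0.91) and Jun (-0.75). The list's median was 0.04 at percentile 93.4, and 11 of its 28 members did not reach the median level over genes on any array. Of 34 pathway components, Jup, which encodes the β-catenin relative plakoglobin, was lower by 15.3-fold (11.06 against 7.12), and Tle5 was lower by 1.22. Their median of -0.0023 did not stand apart.

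Markers of cells other than αβ thymocytes also differed. Of 22 B lymphocyte genes, 6 were higher by at least 2-fold and 1, Ly6d (-1.50), was lower. Their median of 0.83 lay above those of all random lists. Blk, a kinase shared with γδ T cells, was higher by 2.99, Cd79a, a chain of the B cell receptor, by 2.53, Fcmr, the IgM Fc receptor, by 1.86 and Ms4a1, which encodes CD20, by 1.64. Of 27 genes of γδ T, innate-like and NK cells, Blk, Gzma (2.65), Cd160 (2.12) and Sox13 (1.95) were higher, Klrb1c was lower (-1.06), and the median was 0. Of 11 type 17 genes, 3 were higher by at least 2-fold: Blk, Maf (2.86), a transcription factor, and Il23r (1.08). Their median was 0.32, at percentile 99.9. Of 28 myeloid genes, 3 were higher: Ly86, a partner of a Toll-like receptor homologue (4.01), Cybb, an NADPH oxidase subunit (1.55), and Lyz2, lysozyme (1.12). Their median was 0.21, above all random lists. The median was 0.06 over 20 dendritic cell genes and 0.03 over 20 thymic epithelial genes, and neither list stood apart. Plac8 (2.08) and H2-Aa, a class II MHC chain (1.11), were higher among the first, and Cldn4, a claudin (-1.44), was lower among the second. Many members of these lists were dim: on no array did 14 of the 20 thymic epithelial, 9 of the 20 dendritic, 12 of the 28 myeloid, 12 of the 27 γδ, innate and NK and 5 of the 11 type 17 genes reach the median level over genes.

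**Figure D1:**
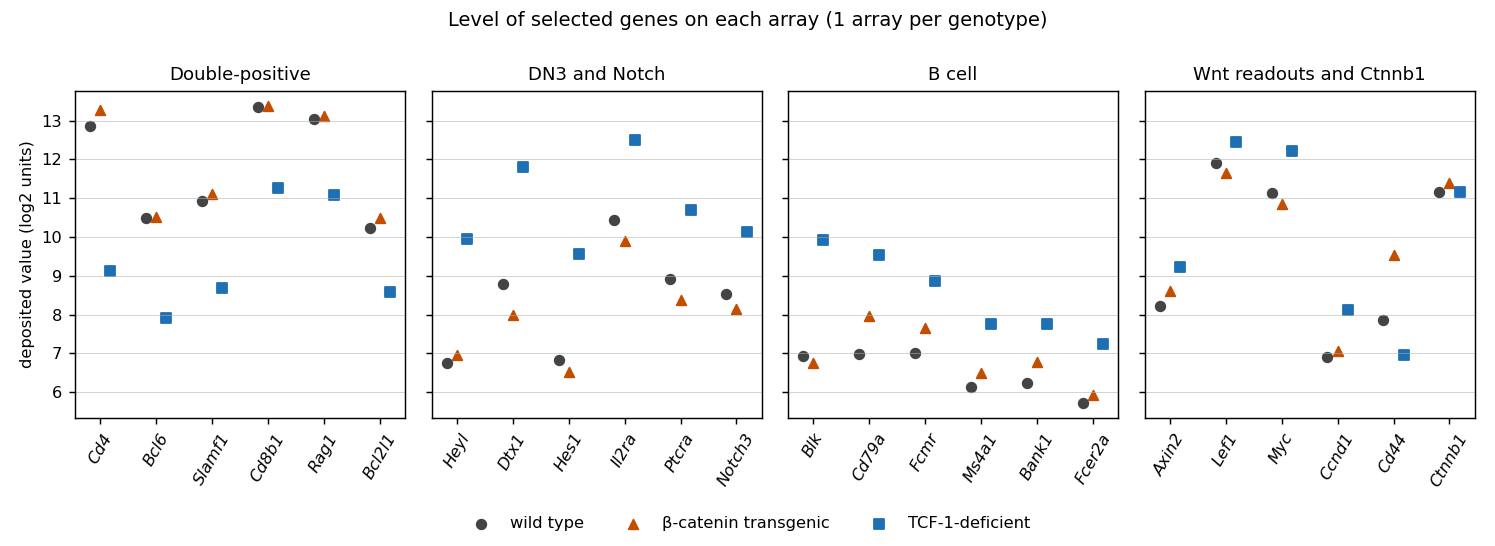
Deposited log2 value (vertical axis) of 24 genes on the 3 arrays, with 1 point per array: grey circles for wild type, orange triangles for β-catenin transgenic and blue squares for TCF-1-deficient. The TCF-1-deficient values lie below the other arrays for the plotted double-positive genes and above them for the plotted DN3, Notch and B cell genes. Cd44 is highest on the transgenic array at 9.54. The genes of every panel are a selection. Rag1 (-1.95), also in the DN3 list, is plotted only with the double-positive genes, and the double-positive gene Cd2 (-0.03) is not shown. Of the B cell genes, Ly6d, which was lower (-1.50), is not shown, and Fcer2a was chosen after its value was seen. These differences are TCF-1-deficient minus wild type.

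Beyond the lists, the lowest genes relative to wild type on the TCF-1-deficient array, among those the rule for named genes admits, were Dgkeos (-4.14), Jup (-3.94), Anxa2, an annexin (-3.83), Cd4, Slc6a19, a neutral amino acid transporter (-3.74), Slc7a11, the cystine-glutamate exchanger (-3.56), F13a1, a chain of coagulation factor XIII (-3.54), Sgk3, a kinase (-3.35), Map4k5, a kinase (-3.22), and Wdr78 (-3.19). Dgkeos is named as the opposite strand of Dgke, which was chosen after its values were seen and was lower by 2.77, so signal of the pair may be shared between strands. The highest were Pdgfrb, a receptor for platelet-derived growth factor (4.47, or 22.2-fold), Fbp1, a gluconeogenic enzyme (4.32), Mpzl2 (4.13), Ly86 (4.01), Atp8a2 (3.92), Igf2bp3, an mRNA-binding protein of fetal cells (3.63), Bst1 (3.58), Uaca (3.52), Afdn (3.31) and Gfra1, a GDNF receptor (3.31). On the wild type array Fbp1, Atp8a2, Igf2bp3, Bst1, Uaca and Afdn were below the median level over genes (6.90). On the TCF-1-deficient array Slc6a19, F13a1, Sgk3 and Map4k5 were below it. The sizes of these differences are therefore uncertain. Pdgfrb stood apart from the other fibroblast and endothelial markers, which were within 2-fold. The median of that list was 0.12, at percentile 98.9.

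The second comparison asked which genes respond to the β-catenin transgene. Far fewer genes differed: of 19938 genes, 30 were higher and 19 lower by at least 2-fold on the transgenic array than on the wild type array. Without the genes of chromosomes X and Y the numbers were 26 and 18. Cecr2, a chromatin remodelling factor, was higher by 28.8-fold, from 6.10 to 10.94, and was at 5.37 on the TCF-1-deficient array. Its wild type value was below the median level over genes (6.90), so the size of this fold is uncertain. Among genes the naming rule admits, which leaves out the dimmer Y-linked genes given above, the next highest were Igkv10-96, an immunoglobulin light chain segment (1.97), Ptpn14, a phosphatase (1.78), Esrp2, a splicing regulator (1.78), Ctsl, the protease cathepsin L (1.71), Cd44 (1.68), Dact1, a regulator of Wnt signalling (1.60), Camk1g (1.37), Papss2, which makes the sulfate donor of the cell (1.29), and Mn1 (1.25). Immunoglobulin segments have close relatives that can share signal, so the value of Igkv10-96 is uncertain. Ptpn14 was higher on the TCF-1-deficient array too (1.92). Dact1, at 6.54 on the wild type array, was also below the median level over genes there, so its fold is uncertain too.

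After Xist, the lowest genes by the same rule on the transgenic array were Slc6a19 (-2.54), Epsti1, an interferon-induced gene (-2.50), Rab6b, a Rab GTPase (-2.28), Fosb (-2.09), Igha, the IgA constant region (-1.72), Dnajc15 (-1.67), Fos (-1.40), Phxr4 (-1.23) and Rtp4, an interferon-stimulated gene (-1.22). Igha differed between its probe sets, with a mean over them of -1.12. All of these except Igha and Rtp4 were lower by at least 2-fold on the TCF-1-deficient array as well. Rtp4 was higher there, by 1.23. Slc6a19, Rab6b and Rtp4 were below the median level over genes on the transgenic array, so the sizes of their differences from wild type are uncertain.

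Between the transgenic and wild type arrays, 12 of 34 gene lists stood apart. The sex-linked list had a median of 3.60, and the medians of the others were small. Single-positive genes had a median of -0.30 over 26 genes, with 0 beyond 2-fold, and Ccr7, the receptor that guides mature thymocytes (-0.76), and S1pr1, the egress receptor (-0.81), among the lowest. Notch readouts had a median of -0.29, regulatory T cell genes of -0.29, T cell receptor-induced genes of -0.25, interferon-stimulated genes of -0.18, immediate early genes of -0.17, cell cycle genes of -0.13 and γδ, innate and NK genes of -0.11. All 8 of these medians lay below those of all 10000 random lists, though some of these lists share members. In these 8 lists, the members beyond 2-fold were Nrp1 (-1.16), Rtp4, Fosb and Fos, each lower. DN3 genes had a median of -0.04, which became 0.04 when arrays were centred on their medians. Centring adds 0.08 to every difference on this array, so it also brings the small negative medians above closer to no difference. Double-positive genes had a median of 0.07 at percentile 99.5. B lymphocyte genes had a median of 0.14, above all random lists, with Cd79a (0.97) and Fcmr (0.63) the highest. Wnt readouts had a median of 0: Cd44 was the 1 of 28 beyond 2-fold, Axin2 was higher by 0.37, and Myc and Lef1 were lower by 0.29 and 0.27. Bcl2l1 was higher by 0.25 and Mcl1 by 0.16, and Bcl2 was lower by 0.24. Of the pro-apoptotic BCL-2 family, Bmf was lower by 1.09.

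**Figure D2:**
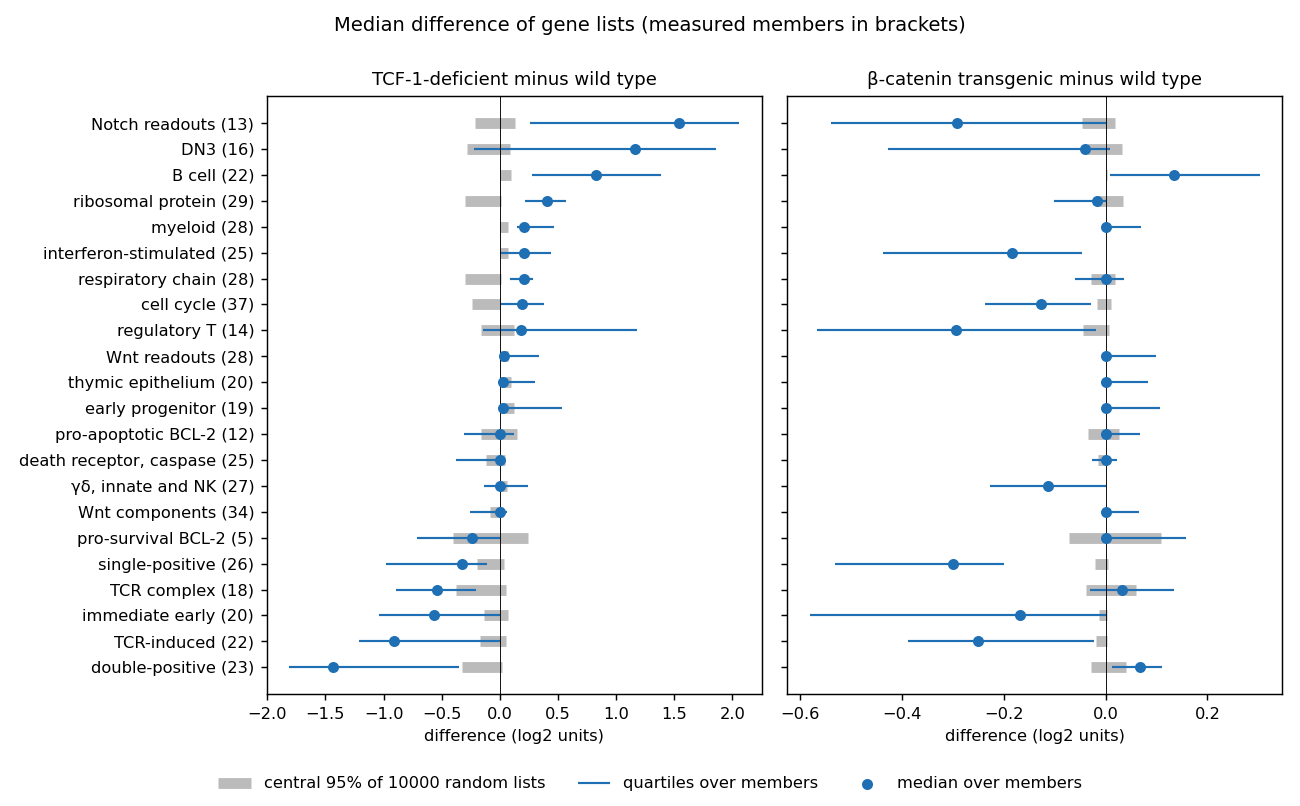
Median difference from wild type in log2 units (horizontal axes, which differ in scale between the panels) of 22 gene lists, for TCF-1-deficient on the left and β-catenin transgenic on the right. Points are medians over measured members, blue lines their quartiles and grey bars the central 95% of 10000 random lists; the double-positive list lies at -1.44 on the left and 0.07 on the right.

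The third comparison combined the others, as the series' design states, to find genes lower without TCF-1 and higher with transgenic β-catenin. At 2-fold in each, 6 genes met both conditions: Ctsl, Papss2, Esrp2, Smoc1, Lamc1 and H2-Q2. Ctsl was lower by 1.78 on the TCF-1-deficient array and higher by 1.71 on the transgenic array. Papss2 differed by -2.89 and 1.29, Esrp2 by -1.14 and 1.78, Smoc1, a secreted matrix protein, by -2.72 and 1.12, Lamc1, a laminin chain, by -1.09 and 1.16, and H2-Q2, a class I MHC gene with close relatives that can share signal, by -1.02 and 1.08. Independent lists of these sizes would share 0.787 genes. On the TCF-1-deficient array Papss2 and Smoc1 were below the median level over genes, so the sizes of their differences there are uncertain. At 1.5-fold in each, 35 genes met both conditions, against 6.69 for independent lists. Independent lists are a reference for size and not a test, since both comparisons use the wild type array, and each of the other combinations was above it too. The next by rank were Nav2 (-1.32 and 0.98), Cd44 (-0.91 and 1.68), Ndrg3 (-0.90 and 1.25), Anxa5, an annexin that binds phosphatidylserine (-1.83 and 0.86), Hsd11b1, which regenerates active glucocorticoid (-1.59 and 0.83), Map4k5 (-3.22 and 0.76), Tiparp (-2.28 and 0.75), Dnajb4, a heat-shock protein (-0.92 and 0.74), Cers6, a ceramide synthase (-0.94 and 0.73), and Cecr2 (-0.72 and 4.85). Of the lists of double-positive, BCL-2 family and death receptor genes, 0 members were among the 35. The combination holds 35 of 19938 genes and these lists are short, so a count of 0 was close to certain. It says nothing about these genes. Bcl2l1 differed by -1.65 and 0.25.

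At 1.5-fold, 75 genes were lower in both genotypes against 9.18 for independent lists, 28 were higher in both against 3.92, and 22 were higher without TCF-1 and lower with the transgene against 5.38. At 2-fold, 14 genes were lower in both genotypes against 0.498 for independent lists, 9 were higher in both against 0.400, and 2, Nrp1 and Rtp4, were higher without TCF-1 and lower with the transgene against 0.253. A deviation of the shared wild type array moves both differences the same way, so it adds to the genes lower or higher in both and not to the opposite combinations. Among the 7304 genes with 3 different values, the transgenic array was in the middle for 53.9%, the wild type array for 39.6% and the TCF-1-deficient array for 6.56%. The order TCF-1-deficient, wild type, transgenic from low to high held for 1443 genes (19.8%) and the reverse for 1448 (19.8%), so neither direction prevailed. Across the 19938 genes, which are not independent replicates, the differences had a Pearson correlation of 0.16 and a Spearman correlation of 0.25. Among genes at or above the median level the Pearson correlation was 0.0876. Simulated unchanged arrays sharing a control gave 0.50 and 0.48. The simulation gave all 3 arrays equal noise, which by itself sets the Pearson correlation near 0.50. The deposited values are unlike it: the variance was 0.189 for the TCF-1-deficient and 0.0307 for the transgenic difference, and many values are identical. The simulated values are therefore no level to hold the observed correlations against. The observed covariance was 0.0121. Without replicates the part of it due to noise on the wild type array is not known.

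**Figure D3:**
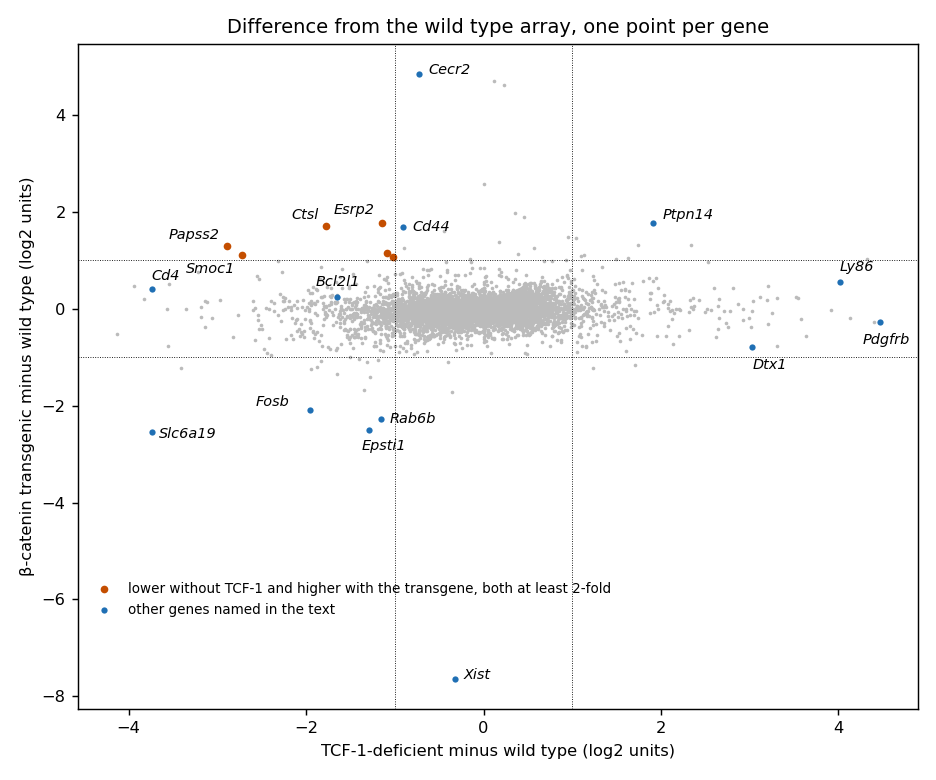
Difference from the wild type array in log2 units for each of 19938 genes (grey points), TCF-1-deficient on the horizontal axis and β-catenin transgenic on the vertical axis, with dotted lines at 2-fold. Blue points are other named genes, the 6 orange points are the genes lower without TCF-1 and higher with the transgene, and the cloud is wider along the horizontal axis, with 789 genes beyond 2-fold against 49.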

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

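Leaving out the genes of chromosomes X and Y, and leaving out genes with identical values for the correlation, were chosen after seeing the data. The counts depended on the size threshold, which by construction passes more or fewer genes. At 1.5-fold, 1376 genes were lower and 806 higher on the TCF-1-deficient array, 133 lower and 97 higher on the transgenic array, and 35 in the combination. At 3-fold the numbers were 175 and 107, 7 and 11, and 1. Under the other settings, 30 of 40 alternative counts, the threshold ones being the remaining 10, stayed within 1.5 times the main count. The correlation of the differences across genes was 0.0876 among genes at or above the median level, and the cause was not tested. Of 1974 recomputed differences of named genes, 1973 moved by less than 1.5-fold, and the exception was Igha with the mean of its probe sets (-1.12). This is a weak check, since most of these settings could hardly move a difference. The filter on dim genes leaves each difference as it was, centring adds a constant, and only 999 of all genes have more than 1 probe set. Of 340 recomputed list medians, 334 neither moved by 1.5-fold nor changed the direction of a list that stood apart. A limit of 1.5-fold exceeds every median on the transgenic array except the sex-linked one, so it says little about those. The DN3 median on the transgenic array became 0.0395 with centred arrays, which adds 0.08 to every difference there and 0.13 on the TCF-1-deficient array. Among genes at or above the median level, fewer members were left: the sex-linked median on the transgenic array became -7.63, the erythroid median without TCF-1 0.72, and the adipocyte medians 1.95 and 0.65. The mean over sex-linked genes on the transgenic array was 1.07. Of 68 list percentiles, 61 kept their side of the limits with random lists not matched on expression, and 7 came to stand apart. No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. Identical values between arrays limit what dim genes show.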

Other observations

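The tests of a floor under low values, of the share of double-positive cells, of B cells and of an effect particular to the transgenic mouse were chosen after the results were seen. Several gene groups not described above had higher medians on the TCF-1-deficient than on the wild type array. Of 29 ribosomal protein genes, 0 passed 2-fold in either direction and 6 were higher by at least 1.5-fold, with a median of 0.41 and the largest difference in Rps19 (0.998). Of 28 genes of the respiratory chain, 0 passed 1.5-fold, with a median of 0.21. Of 37 cell cycle genes, 4 were higher by at least 1.5-fold and 0 lower, with a median of 0.19, and the replication helicase genes Mcm3 (0.69) and Mcm7 (0.63) were the highest, while Mki67 was at -0.28. These 3 medians lay above those of all random lists. Of 17 glycolysis genes, Tpi1 (1.18) and Hk2, a hexokinase (1.06), were higher by at least 2-fold, Pdk1, a kinase that restrains pyruvate oxidation, was at -0.99, and the median was 0.12 at percentile 98.9. Centred arrays add 0.13 to each of these differences.

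Of 25 interferon-stimulated genes, 3 were higher without TCF-1 by at least 2-fold, Usp18 (1.96), Oasl2 (1.43) and Rtp4 (1.23), with a median of 0.21, while on the transgenic array the same 3 differed from wild type by -0.57, -0.44 and -1.22. Of 14 regulatory T cell genes, 4 were higher without TCF-1, Gpr83 (2.21), Il2ra (2.06), Nrp1 (3.26-fold) and Izumo1r (1.32), with a median of 0.18 at percentile 99.3, and 2 were lower by at least 1.5-fold, Tnfrsf18 (-0.93) and Tnfrsf4 (-0.87). On the transgenic array the 4 higher genes differed by -0.57, -0.56, -1.16 and -0.27. Il2ra is also in the DN3 and Notch lists and Gpr83 in the glucocorticoid list, so the regulatory T cell list is not independent of those. Lists that did not stand apart without TCF-1 were glucocorticoid response genes, with a median of -0.24, Gpr83 at 2.21 and Klf13 at -1.16, memory-like CD8 T cell genes, with a median of 0 and Cd44 at -0.91, cholesterol synthesis genes, with a median of -0.00067 and Insig1 at -0.79, erythroid genes, with a median of 0, Car2 at -1.15 and Alas2 at 1.14, adipocyte genes, with a median of 0 and Scd1 at 1.95, and sex-linked genes, with a median of 0.06. On the transgenic array the sex-linked median was 3.60, the glucocorticoid median -0.04, the ribosomal median -0.02 and the T cell receptor complex median 0.03, and the lists not named above for that array had a median of 0.

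Among the 12146 probe sets without a name here, 20.1% were lower by at least 2-fold on the TCF-1-deficient array and 0.96% higher, against 2.80% and 1.38% of the named ones. On the transgenic array, 7.81% of the unnamed probe sets were lower than wild type by at least 2-fold and 0.45% higher, against 0.12% and 0.17% of the named ones.

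A first pattern is the identity of values between arrays, in 28.8% of all probe sets. A floor set under low values is argued against: 24.5% of these probe sets lay above the median level, with 3206 different values up to 13.8. Median polish over only 3 arrays, a step of RMA that takes medians over arrays, may produce it. In simulated probe sets with no difference between 3 arrays, it gave identical values on all 3 in 78.0% of sets with 25 probes, 25.2% with 12 probes and 0% with 4 probes. No biological explanation was tested.

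A second pattern is the lower double-positive genes and higher DN3 and B lymphocyte genes without TCF-1. A lower share of double-positive cells with all other cell types raised alike cannot be told apart from other causes: the DN3 median exceeded the single-positive median by 1.56 (15 and 25 genes), but the 95% bootstrap interval over members, 0.20 to 2.48, includes gaps under 0.5, and single-positive genes may also be expressed in double-positive cells. The bound of 0.5 was lowered to 0 after the interval was seen, where the interval would exclude this explanation, and then restored, so the test decides nothing. The higher DN3 genes in it are also mostly Notch readouts, so the gap may not be particular to the DN3 stage. More B cells in the suspension and a change per cell cannot be told apart either. Of 13 B lymphocyte genes that are in no other list and reach the median level, 9 were higher by at least 1.5-fold, with Cd79a at 9.52. The count restates the difference of the list. Ly6d was lower, and Ighm, chosen after its value was seen and then required by the test, was identical on both arrays. Neither decides the question: Ly6d was at 12.26 on the wild type array against 6.99 for Cd79a, and an identical value is not a measured equality. A block at the DN3 stage and the age of 8 weeks stay open and untested.

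Another pattern is that genes past 2-fold lie near each other: on the transgenic array 8 of 44 autosomal genes had another within 5 genes, where 2000 random sets had a median of 0, exceeded 4 in at most 2.5% and reached 8 at most, and on the TCF-1-deficient array 327 of 763 did, where random sets had a median of 253 and reached 316 at most. Shared signal within gene families is only weakly argued against as the whole cause on the transgenic array. Without pairs of like symbols 6 remained: Dnajc15, Epsti1, Prkaa2, Plpp3, Il12rb2 and Igkv10-96. Random sets treated the same way exceeded 4 in at most 2.5%. However, the value of Igkv10-96 may itself rest on shared signal, and its neighbour may count only through it. Of the 8, 7 were past 2-fold in the same direction on the TCF-1-deficient array (Ifi208 and Ifi209 besides those named, and not Igkv10-96), as were 23 of all 49 genes past 2-fold on the transgenic array, and the shared wild type array favours such agreement. Between the transgenic and TCF-1-deficient arrays, which leaves the wild type array out, 2 of the 8 were past 2-fold, Epsti1 and Igkv10-96, so a haplotype or transgene effect particular to the transgenic mouse, a difference of the wild type mouse from both others and joint control of adjacent genes could each contribute and stay open. Prkaa2, Plpp3, Il12rb2, Ifi208 and Ifi209 were chosen after their values were seen.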
